A study of Rattus norvegicus with 12 samples.

How the data were processed

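RNA recovered with an antibody against the protein Cpeb4 was measured in ventricular cardiomyocytes (heart muscle cells) of neonatal Wistar rats. The cells had received either a mock treatment or phenylephrine (PE), an agonist of alpha-adrenergic receptors that induces cardiomyocyte hypertrophy, for 24 h. Per the labels' protocols, Cpeb4, an RNA-binding protein of the cytoplasmic polyadenylation element binding family, was precipitated from the myocytes with an antibody, and RNA was recovered from the precipitate. Total RNA served as input. Libraries were made from 200 ng of RNA with a 3′ end sequencing kit, which reads the end of each transcript and not its whole length, with 15 cycles. The 12 libraries form 4 groups of 3, namely input and immunoprecipitate (IP) of mock cells and of PE cells. No precipitate made without the Cpeb4 antibody was analysed here.

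The values are the raw counts per gene that the authors deposited as 1 table, with Ensembl rat gene identifiers and no normalization. The submitters' processing notes name cutadapt 2.5, STAR 2.7, featureCounts 1.6.4, DESeq2 and the genome build Rnor_6.0, and the options used are not given in the sources used here. The table held 32883 genes and 32883 blank lines, which were skipped, and 15786 genes had at least 1 count. Columns were matched to samples by sample type, treatment and replicate number. The files do not pair the identifiers with gene symbols. The reference table used here, of 47357 rat genes on the GRCr8 assembly, holds 0 Ensembl identifiers, so 0 identifiers could be given a name. For this reason the 36 gene lists fixed before the data were examined, the value of the Cpeb4 transcript itself and a test of cytoplasmic polyadenylation motifs in 3′ untranslated regions could not be run, and at most 2 identifiers per direction and comparison are printed.

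Library totals ranged from 1423334 to 30216559 counts, a 21.2-fold span. Counts without molecular identifiers are not independent molecules, so a floor of 3 counts, used where a group had none, covers counting error only. Libraries of 1 group were compared by chi-square over genes with at least 20 counts. The lowest value per degree of freedom was 7.79, so no pair agreed within sampling noise and each library was kept as 1 replicate. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

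Tests used edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr (10491 genes kept, holding at least 99.6% of each library's counts), robust dispersion estimates and the quasi-likelihood F-test. A single fit held the 4 group means of all 12 libraries. The 5 contrasts were IP against input in mock cells, the same in PE cells, the difference between these, PE against mock in input, and PE against mock in IP. P-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, and an adjusted p under 0.05 was the threshold. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Normalised counts are given in CPM, counts scaled to a common library total, computed from the deposited counts with TMM factors. A log2 fold change of IP against input is relative to the TMM scaling, which sets most genes near 0, and is not a ratio of shares of the raw counts. It does not give the amount of RNA recovered.

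Test, samples, alternatives, and the rule for the genes named were chosen before the data were examined. The rule took genes past the threshold with a mean of at least 10 CPM over both groups and no overlap between the libraries of the groups, the largest log2 fold changes first. The rule also asked for a gene symbol and allowed 12 genes per direction. As no symbols were at hand, the identifiers stand for the symbols and 2 per direction are given. Shares of counts were compared by two-sided exact permutation tests of the difference in means, within each treatment and over both treatments with labels permuted within treatment. With 3 libraries against 3 such an exact permutation test cannot go below p = 0.1.

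Alternatives were DESeq2 size factors, library totals without composition factors, no filter, the Wald test of DESeq2 1.42.0, fits of 6 libraries, replicate blocks and leaving out each library. Alternatives added after the data had been seen were leaving out or modelling the 4 libraries of mock replicate 2 and PE replicate 1, limma 3.58.1 voom with sample quality weights, the IP effect averaged over both treatments, other rankings of the most abundant features, and, for named genes, fits of 6 libraries and the block within treatment.

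The steps were tested on simulated counts with the spread and depths of these libraries and each gene's mean over all 12 libraries. Of 10491 genes, 200 were changed, drawn from those with a mean of at least 10 CPM. The simulated input and IP thus differed in the changed genes alone, and no libraries deviated together. How the steps handle a difference in composition, or libraries that deviate together, was not simulated. For IP against input in mock cells, 24 of 100 genes changed 4-fold and 60 of 100 changed 16-fold were recovered, with 9 false calls. For PE against mock in input, 22 of 100 and 63 of 100 were recovered, with 4 false calls.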

Results

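RNA precipitated with an antibody against Cpeb4 was profiled in neonatal rat ventricular cardiomyocytes under mock treatment and after PE, with 3 libraries each of input and IP RNA per treatment. The design asks which transcripts are more or less abundant in the Cpeb4 precipitate than in the input, whether PE alters that enrichment, and what PE changes in either RNA pool. Mock input totals were 8479083, 4981399 and 1423334 counts in replicates 1, 2 and 3, and PE input totals were 5167090, 5139592 and 29538785. Mock IP totals were 5030021, 17838962 and 15448755, and PE IP totals were 30216559, 2224005 and 5053801. Between 8455 and 11822 genes had a count in a library.

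A few highly abundant transcripts dominated the input and took a far smaller share of the Cpeb4 precipitates. The 10 most abundant features, ranked by their mean share over all libraries, held 49.7% ± 14.7 (SD, n = 3) of counts in mock input and 14.6% ± 7.24 (n = 3) in mock IP. In PE cells they held 39.6% ± 11.7 (n = 3) of input and 11.7% ± 4.30 (n = 3) of IP. Shares in the 6 precipitates lay between 6.23% and 19.2%, all below the lowest of the 6 inputs at 26.6%. Exact permutation tests gave p = 0.1 in each treatment, the smallest value possible, and p = 0.005 over both treatments, also the smallest possible (0.0075 after Benjamini-Hochberg adjustment over 3 measures). The number of genes that together held 50% of the counts was 5 to 55 in input and 157 to 282 in IP (exact permutation p = 0.005, adjusted 0.0075). The feature with the highest mean share over all libraries held 3.12% to 23.1% of input and 0.85% to 7.45% of IP (exact permutation p = 0.3 in mock, 0.2 in PE and 0.04 over both, adjusted 0.04). A ranking over all libraries favours features abundant in input, whose shares were larger. Ranked within each library instead, a choice added after the data had been seen, the 10 most abundant features held 30.03% to 61.9% of input and 11.4% to 19.8% of IP (exact permutation p = 0.005, the smallest possible).

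**Figure D1:**
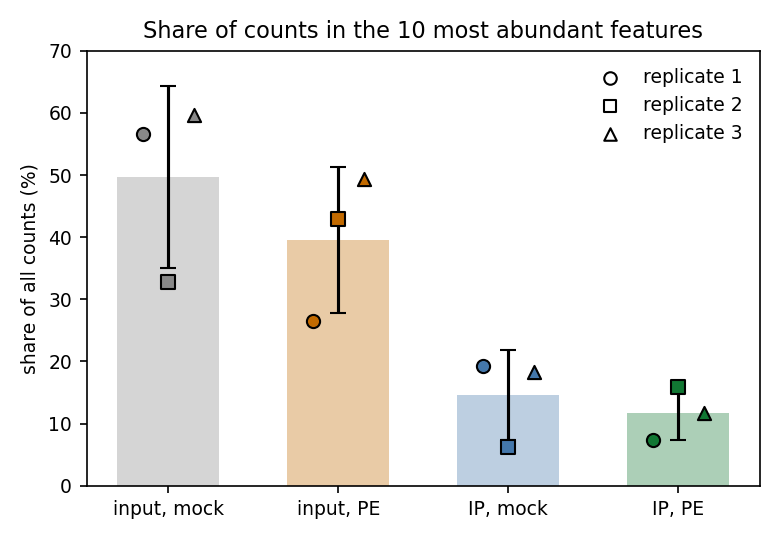
Share of all counts, in percent, held by the 10 most abundant features in each of the 4 groups. Points are libraries, bars are means and error bars are SDs (n = 3); the 6 IP libraries lie between 6.23% and 19.2%, below all 6 input libraries.

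In mock cells, 61 genes were lower and 17 were higher in the Cpeb4 precipitate than in input (edgeR quasi-likelihood test, adjusted p under 0.05, 10491 genes). The depleted genes were abundant ones, with a median of 885 CPM against 12 CPM for all genes tested, and the enriched genes had a median of 57.5 CPM. The 61 depleted genes held 24.3% ± 4.53 (SD, n = 3) of input counts and 8.35% ± 1.48 (n = 3) of IP counts. The 17 enriched genes held 0.0261% ± 0.00926 (n = 3) of input and 0.285% ± 0.123 (n = 3) of IP. These shares describe the genes only, since the genes were chosen for this difference in the same libraries. All 78 genes differed by at least 2-fold. Of all genes tested, 17.9% had no overlap between the 3 IP and the 3 input libraries. Random splits give 10% on average. Genes of 1 library can vary together, so a single split can lie away from 10%, and the departure was not tested.

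The enriched gene ENSRNOG00000004246 rose from 5.07 ± 3.73 CPM (SD, n = 3) in mock input to 74.5 ± 31.7 CPM (n = 3) in mock IP, a log2 fold change of 3.78 (SE 0.58, edgeR adjusted p = 0.00811). It did not pass without input mock replicate 1 or IP mock replicate 3 (edgeR adjusted p = 0.0807 and 0.0648). ENSRNOG00000015772 went from 0.935 ± 0.833 to 45.3 ± 52.9 CPM, a log2 fold change of 5.29 (SE 1.16, edgeR adjusted p = 0.0439). Its IP level was 106 CPM in replicate 2 and 12.1 and 17.5 CPM in the others, and without IP mock replicate 2 the log2 fold change was 3.68 (edgeR adjusted p = 0.213). Among depleted genes, ENSRNOG00000043866 held 137091 ± 20037 CPM in mock input and 10872 ± 3520 CPM in mock IP (log2 fold change -3.66, SE 0.54, edgeR adjusted p = 0.0124). It did not pass without input mock replicate 1 (edgeR adjusted p = 0.0618) or without IP mock replicate 1, 2 or 3 (0.0723, 0.0899 and 0.0756). ENSRNOG00000056721 had 497 counts in the 3 mock inputs and 0 in the 3 precipitates, at least 700.7-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0384). Input mock replicate 2 held 452 of these counts, and without it the bound was 109-fold and the gene did not pass (edgeR adjusted p = 0.198).

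Scaled by library totals without composition factors, the same contrast had 842 genes higher and 10 lower, a split of 98.8% against 21.8% higher, with a shift of the median log2 fold change of all genes of 1.21. Fitted on the 6 mock libraries alone, 0 genes were higher and 13 lower, whereas the DESeq2 Wald test gave 126 and 281 and the edgeR fit without a filter 156 and 191. A replicate block within treatment, which takes input and IP of the same number as paired, gave 95 and 177. Without input mock replicate 1, or without IP mock replicate 3, 0 genes passed in either direction. The higher and lower counts were 2 and 14 without input mock replicate 3, 1 and 4 without IP mock replicate 1, 1 and 12 without IP mock replicate 2, 2 and 18 without input PE replicate 2, 9 and 51 without input mock replicate 2, 8 and 54 without IP PE replicate 1, and 6 and 43 without IP PE replicate 2.

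In PE cells, 173 genes were lower and 48 were higher in the precipitate than in input (edgeR, adjusted p under 0.05). The depleted genes again had high levels, with a median of 289 CPM against 12.9 CPM for all genes, and the enriched genes had a median of 65.5 CPM. The depleted genes held 31.2% ± 4.93 (SD, n = 3) of PE input counts and 13.2% ± 2.20 (n = 3) of PE IP counts, and the enriched genes 0.169% ± 0.0468 and 1.37% ± 0.272. Here too the genes were chosen for this difference in the same libraries. All 221 genes differed by at least 2-fold. Of all genes tested, 22.2% had no overlap between IP and input libraries, where random splits give 10% on average. This departure was not tested either.

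ENSRNOG00000061441 fell from 47.0 ± 30.7 CPM (SD, n = 3) in PE input to 2.08 ± 1.05 CPM (n = 3) in PE IP, a log2 fold change of -4.44 (SE 0.78, edgeR adjusted p = 0.00657). ENSRNOG00000031053 fell from 476 ± 350 to 27.7 ± 15.7 CPM (log2 fold change -4.12, SE 0.89, edgeR adjusted p = 0.0356), a call lost in 8 of 12 fits that left out 1 library, with adjusted p up to 0.143. ENSRNOG00000023356 rose from 1.59 ± 0.450 to 37.5 ± 24.7 CPM (log2 fold change 4.57, SE 0.98, edgeR adjusted p = 0.0216). It did not pass without input PE replicate 2 or 3 (edgeR adjusted p = 0.0865 and 0.130) or without IP PE replicate 1 or 2 (0.0585 and 0.134). ENSRNOG00000006738 rose from 0.0995 ± 0.172 CPM, to 21.0 ± 15.7 CPM (log2 fold change 7.12, SE 1.66, edgeR adjusted p = 0.0340). All 5 of its input counts lay in PE input replicate 3. Without that library the input had 0 counts, the precipitate was at least 60.5-fold higher against a floor of 3 counts over the group, and the gene did not pass (edgeR adjusted p = 0.0941).

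**Figure D2:**
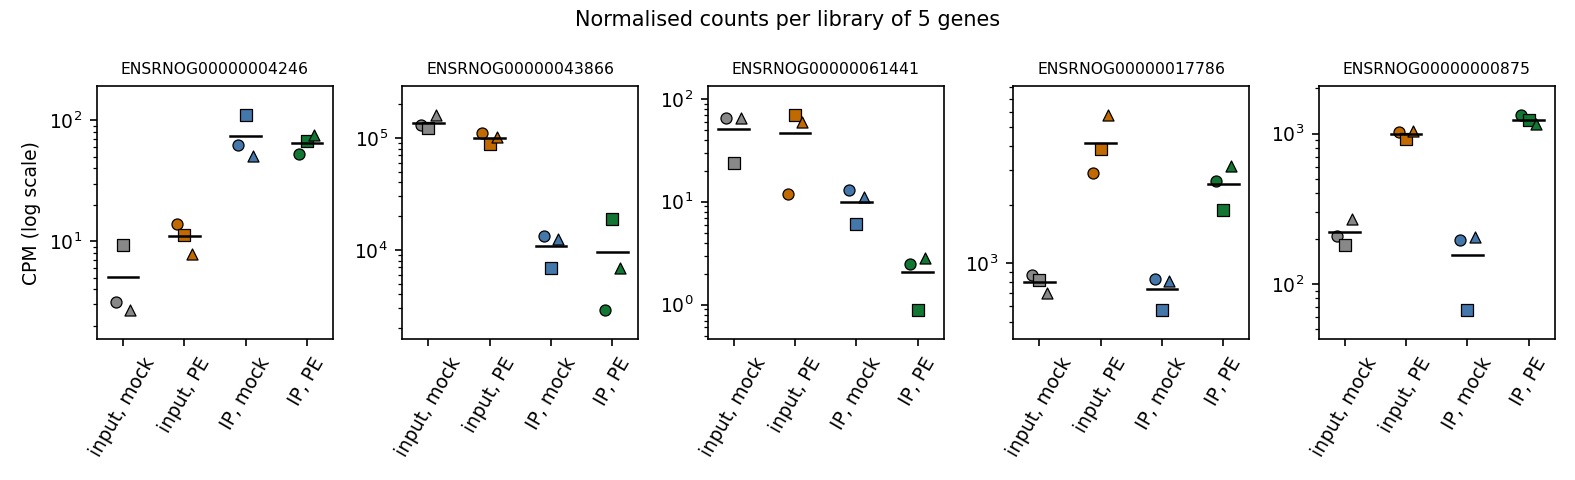
Normalised counts in CPM, on log axes that differ between panels, of 5 genes in the 12 libraries. Points are libraries (circle, square and triangle for replicates 1, 2 and 3) and lines are group means; ENSRNOG00000004246 lay above 50 CPM in every precipitate and below 14 CPM in every input.

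Library totals alone gave 641 genes higher and 24 lower in PE cells, 96.4% against 21.7% higher, with a shift of the median log2 fold change of 1.09. Fitted on the 6 PE libraries alone, 30 genes were higher and 107 lower, whereas the DESeq2 Wald test gave 200 and 383 and the edgeR fit without a filter 158 and 265. A replicate block within treatment, which takes input and IP of the same number as paired, gave 128 and 293. The higher and lower counts were 4 and 96 without input PE replicate 2, 7 and 60 without input PE replicate 3, 9 and 77 without IP PE replicate 1, 3 and 62 without IP PE replicate 2, 37 and 77 without IP PE replicate 3, 28 and 116 without input mock replicate 3, 28 and 131 without IP mock replicate 1, 83 and 249 without IP mock replicate 2, and 24 and 128 without IP mock replicate 3.

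The enrichment profiles of mock and PE cells, which share no library, ran in the same direction for the genes that passed. All 17 genes enriched and all 61 depleted in mock cells had the same sign in PE cells, and all 48 enriched and 173 depleted in PE cells had the same sign in mock cells. The calls overlapped in 6 enriched genes, where independent lists would share 0.0778, and in 47 depleted genes, where they would share 1.01. Both lists came from 1 fit with a shared estimate of the spread of each gene. They are thus not independent, and the excess over these numbers is not a replication. No gene passed in opposite directions, and 1 did when no low-count filter was used. Across all 10491 genes the log2 fold changes of both treatments had a Pearson r of 0.31 and a Spearman rho of 0.40, and 65.3% had the same sign; genes are not independent replicates. Without a filter r was 0.15. With each contrast fitted on its own 6 libraries, which like the fit without a filter was added for the overlap after the data had been seen, 13 genes passed in the same direction in both. All of them were depleted, as 0 genes then passed as higher in mock cells. Leaving out mock replicate 2 and PE replicate 1 of input and IP was a choice made after the data had been seen. It was made because 3 of these 4 libraries lacked many expressed genes. Without these 4 libraries the overlap was 91 enriched genes (5.58 for independent lists) and 274 depleted (20.4 for independent lists). With single libraries left out, also added afterwards, the overlap was 0 genes without input mock replicate 1 and 0 without IP mock replicate 3, as no mock gene then passed. It was 15 without input mock replicate 3, 5 and 13 without IP mock replicates 1 and 2, 19 without input PE replicate 2, and 31, 34, 30 and 32 without input PE replicate 3 and IP PE replicates 1, 2 and 3.

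**Figure D3:**
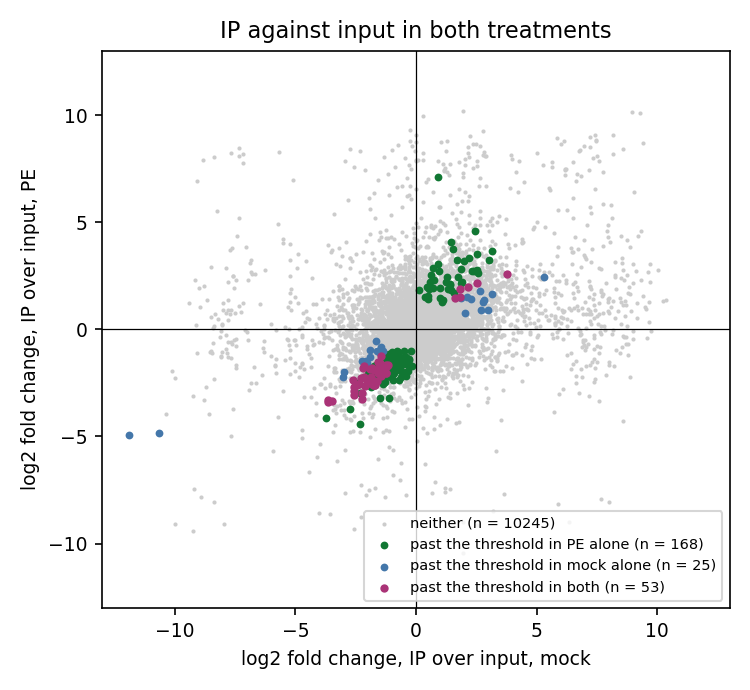
Log2 fold change of IP over input in mock cells (horizontal) and in PE cells (vertical) for 10491 genes, one point per gene. Colours mark genes past the threshold in PE alone, in mock alone or in both; the 53 genes past it in both lie in the lower left (47) or upper right (6).

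No change of IP enrichment with PE was detected for a single gene. The test of the difference between both IP contrasts passed 0 genes higher and 0 lower (edgeR, smallest adjusted p = 1.00), with 271 genes at an unadjusted p under 0.05, and the DESeq2 Wald test passed 2. Detection of such a difference was not simulated. Its median SE was 1.61 on the log2 scale, against 1.15 for IP against input in mock cells. For that contrast the simulation recovered only 60 of 100 genes changed 16-fold. At a gene of typical spread, even a change of enrichment far above a few-fold could thus be missed. The larger number of genes past the threshold in PE than in mock cells is therefore not a shown difference between treatments.

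PE raised 1 gene in the input. ENSRNOG00000017786 went from 798 ± 86.5 CPM (SD, n = 3) in mock input to 4165 ± 1453 CPM (n = 3) in PE input, a log2 fold change of 2.38 (SE 0.31, edgeR adjusted p = 0.00906). In the precipitates the same gene went from 738 ± 143 to 2551 ± 648 CPM (n = 3 each), a log2 fold change of 1.79 (SE 0.31) that did not pass (edgeR adjusted p = 0.116). Of all genes tested, 9.85% had no overlap between PE and mock input libraries, where random splits give 10% on average. No gene passed as lower in the input, with 375 genes at an unadjusted p under 0.05, and the DESeq2 Wald test passed 18 higher and 3 lower. The adjusted p of ENSRNOG00000017786 was 0.115, 0.155 and 0.226 without mock input replicates 1, 2 and 3 and 0.0682 without PE input replicate 3, and 4 genes passed without IP mock replicate 2. Without the 4 libraries of mock replicate 2 and PE replicate 1, 8 genes were higher and 0 lower.

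PE also raised 1 gene in the Cpeb4 precipitates. ENSRNOG00000000875 went from 156 ± 76.9 CPM (SD, n = 3) in mock IP to 1234 ± 83.4 CPM (n = 3) in PE IP, a log2 fold change of 2.99 (SE 0.38, edgeR adjusted p = 0.00565). In the input the same gene went from 220 ± 45.2 to 993 ± 62.9 CPM (n = 3 each), a log2 fold change of 2.17 (SE 0.37, edgeR adjusted p = 0.0663). Relative to the TMM scaling, its log2 fold changes of IP against input were -0.50 (SE 0.35) in mock and 0.31 (SE 0.35) in PE cells. They are not ratios of raw shares, as library totals alone shifted the median log2 fold change of all genes by 1.21 and 1.09. Of all genes tested, 14.9% had no overlap between PE and mock IP libraries, where random splits give 10% on average. The departure from 10% was not tested. No gene passed as lower in the precipitates, with 581 genes at an unadjusted p under 0.05, and the DESeq2 Wald test passed 28 higher and 13 lower. Fitted on the 6 IP libraries alone, 0 genes passed in either direction, and the adjusted p of ENSRNOG00000000875 was 0.569. Without the 4 libraries of mock replicate 2 and PE replicate 1, 19 genes were higher and 17 lower in PE precipitates.

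Some libraries stood apart from the rest of their groups. Among genes at 5 to 10 CPM in the reference libraries of their type, which were the other libraries outside mock replicate 2 and PE replicate 1, 24.2% had 0 counts in input mock replicate 2, 23.7% in input PE replicate 1 and 39.5% in IP mock replicate 2. The other 9 libraries had between 0.824% and 9.79%. At 20 to 50 CPM the 3 libraries lacked 3.31%, 2.76% and 6.96% of genes, and the others at most 0.238%. The common biological coefficient of variation of the fit was 1.00, and 0.627 without mock replicate 2 and PE replicate 1. Without these 4 libraries, IP against input gave 164 genes higher and 344 lower in mock cells and 357 higher and 621 lower in PE cells, and the change of enrichment with PE gave 0 in either direction with 728 genes at an unadjusted p under 0.05.

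**Figure D4:**
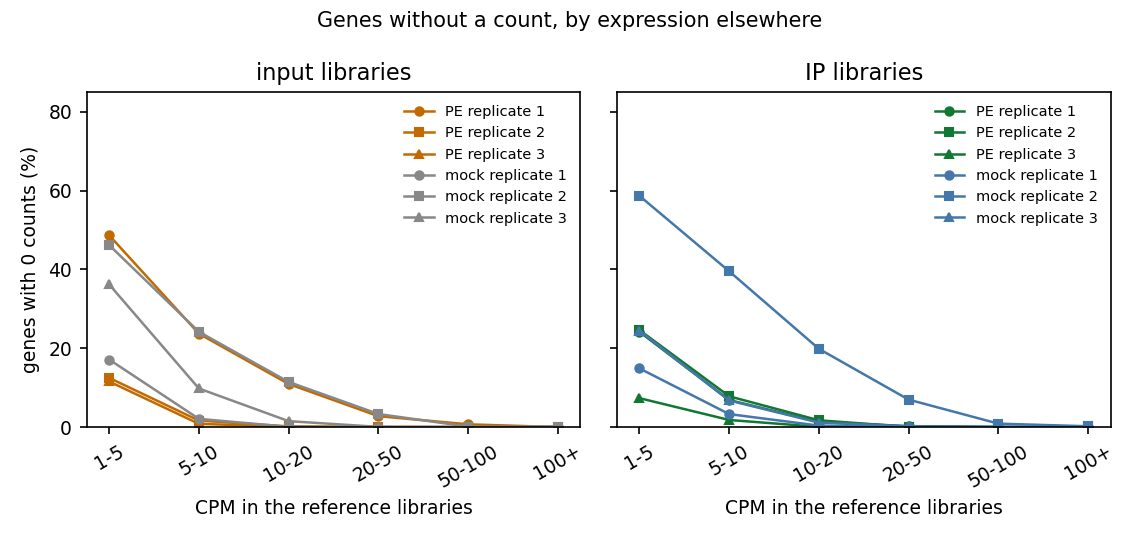
Percentage of genes with 0 counts in each library against the CPM range of the same genes in the reference libraries, for input (left) and IP (right). Each line is a library; input mock replicate 2, input PE replicate 1 and IP mock replicate 2 lie above the others at 5 to 10 CPM, at 24.2%, 23.7% and 39.5%.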

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

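The alternatives that leave out or model the 4 libraries of mock replicate 2 and PE replicate 1, the voom fit and the averaged contrast were chosen after seeing the data; all others were planned unless stated. Counts are given as higher and lower, with 17 and 61 in mock and 48 and 173 in PE for IP against input as reported. DESeq2 size factors gave 17 and 88, and 43 and 172. Library totals gave 842 and 10, and 641 and 24, by construction without correction for composition; 60 of the 61 and 168 of the 173 lower genes kept a negative sign, and 7 and 23 of them passed as lower. No filter gave 156 and 191, and 158 and 265. The DESeq2 Wald test gave 126 and 281, and 200 and 383, and left 6722 genes in mock without an adjusted p. The 6 libraries of a comparison alone gave 0 and 13, and 30 and 107. Leaving out the 4 libraries gave 164 and 344, and 357 and 621, and a term for them 109 and 223, and 192 and 378. Voom gave 77 and 218, and 242 and 365. Leaving out each library gave 0 to 19 and 0 to 71 in mock, and 3 to 83 and 60 to 249 in PE. The cause of these moves was not tested.

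For PE against mock in input (1 and 0 as reported), no filter gave 14 and 1, DESeq2 18 and 3, 6 libraries 2 and 0, leaving out the 4 libraries 8 and 0, their term 6 and 0, voom 5 and 0, and single libraries left out 0 to 4 and 0. For PE against mock in IP (1 and 0), these gave 17 and 13, 28 and 13, 0 and 0, 19 and 17, 8 and 6, and 3 and 1, and single libraries left out 1 and 0. The change of enrichment with PE stayed at 0 and 0, except 1 lower without a filter and 2 lower with DESeq2. Genes past the threshold in the same direction in both IP contrasts numbered 53 as reported, 72 with DESeq2 size factors, 356 with library totals, 13 with each contrast fitted on its 6 libraries, 259 with the DESeq2 Wald test, 210 without a filter (1 gene in opposite directions), 365 without the 4 libraries, 243 with their term, 221 with voom, and 0 to 68 with single libraries left out. For this overlap the DESeq2 Wald test alone was planned and all other alternatives were added after seeing the data.

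No named gene changed sign in its 21 or 22 alternatives, which include the 6-library fit and, for IP against input, the block within treatment, both added after seeing the data. This was likely beforehand, as genes were named only without overlap between the groups. DESeq2 gave no adjusted p for ENSRNOG00000015772 and ENSRNOG00000056721, so the Wald test is not among their alternatives. ENSRNOG00000061441 passed in all 22, with adjusted p up to 0.0492. ENSRNOG00000000875 passed in 20 of 21 and lost the threshold in the 6-library fit. When each of 12 libraries was left out, ENSRNOG00000056721 lost the threshold 10 times, ENSRNOG00000015772 9 times, ENSRNOG00000006738 and ENSRNOG00000031053 8 times each, ENSRNOG00000017786, ENSRNOG00000023356 and ENSRNOG00000043866 4 times each, and ENSRNOG00000004246 2 times. Other losses were ENSRNOG00000056721, ENSRNOG00000015772 and ENSRNOG00000004246 in the 6-library fit, ENSRNOG00000056721 also with the replicate block, without the 4 libraries and with voom, ENSRNOG00000006738 with both replicate blocks, and ENSRNOG00000031053 with the replicate block.

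The replicate number was tried as a pairing. The table's column names give input and IP of the same treatment and number the same letter, and nothing says what the letter marks. Deviations of same-numbered libraries from their group means correlated between -0.223 and 0.242, above 0.1 in 8 of 18 pairs. Input and IP of the same treatment and number correlated between 0.0171 and 0.242, above 0.1 in 5 of 6 pairs, and 9 of 12 libraries correlated best with their own number. Input and IP of the same treatment but other numbers correlated between -0.264 and 0.184, above 0.1 in 3 of 12 pairs. Their median was -0.131, against 0.175 for the same number. Some of these pairs hold 1 library of mock replicate 2 or PE replicate 1. Over all groups, such pairs were above 0.1 in 0 of 24. The shared letter may mark a pairing by design, which the permutation tests did not use, and these correlations cannot decide it. Input mock replicate 2, for example, correlated more with input PE replicate 1 (0.273) than with its own IP (0.242). With the replicate block the counts were 19 and 49 in mock, 34 and 130 in PE, 0 and 0 for the change with PE, and 1 and 0 for PE in input and in IP. With a replicate block within treatment they were 95 and 177, 128 and 293, and 0 and 0. The overlap of both IP contrasts was 44 genes with the first block and 191 with the second.

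Depth ranged 21.2-fold, and the smallest library, input mock replicate 3, held 1423334 counts. The planned gene lists and motif test, with their alternatives, were not run, as no identifier had a symbol.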

Other observations

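All tests of technical explanations below concern patterns seen in the data first; those on depth, on the share of the 10 most abundant features and on the antibody were chosen only after the result was seen, as were the averaged contrast and the other rankings of features. The splits of the averaged contrast were fixed before they were counted.

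Averaged over both treatments, 237 genes were higher and 380 lower in IP than in input (edgeR, adjusted p under 0.05). Library totals alone turned this balance, to 2823 higher and 65 lower, and leaving out single libraries gave 119 to 279 higher and 258 to 429 lower. The DESeq2 Wald test gave 493 and 605, no filter 411 and 491, and voom 692 and 708. Leaving out the 4 libraries of mock replicate 2 and PE replicate 1 gave 670 and 859, and a term for them 498 and 589. Of the 10 most abundant features, 6 were lower and 0 higher, with log2 fold changes between -3.60 and -0.30. Of 100 splits that permuted input and IP within each treatment, 1, the real one, gave as many as 617 genes, and the highest of the others gave 57. Random assignment of input and IP among these 12 libraries is thus argued against, for a contrast chosen after the data had been seen. As the replicates may be technical, this does not extend to other cultures or animals.

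For the separate contrasts, 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 78 genes for IP against input in mock cells, 221 in PE cells, 1 for PE against mock in input and 1 in IP, and in each case the highest of the other 9 splits gave 0, so that 1 of the 10 splits gave as many. For the change of enrichment with PE, the real count was 0 genes, which every split reaches. The 50 splits, of which the highest gave 3 genes, therefore cannot decide anything about chance here.

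The smaller share of the 10 most abundant features in the precipitates was weighed against technical explanations. Mock replicate 2 and PE replicate 1 were left out of input and IP. The highest IP share was then 19.2% and the lowest input share 42.9% (exact permutation p = 0.0556, the smallest possible). This separation was fixed beforehand, as all 12 libraries were already separated, and it cannot decide anything. The size of the difference could have shrunk. Averaged over both treatments, IP minus input was -35.8 percentage points without these 4 libraries and -31.5 with all 12. These sizes argue against a difference carried by the 4 libraries. Neither the scaling nor a ranking that favours input is the whole cause, since shares are taken from raw counts and, for the 10 features ranked by the IP libraries alone, were 7.81% to 18.7% in IP and 27.5% to 53.8% in input. Carry-over of RNA that does not depend on the antibody stays open, because 0 of the 12 libraries came from a precipitate without it, and this cannot be told apart from binding to Cpeb4. Selective binding by Cpeb4 may lower the share of abundant transcripts, and so could non-specific recovery that evens out abundance.

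Input mock replicate 2, input PE replicate 1 and IP mock replicate 2 lacked many genes expressed elsewhere. Shallow sequencing is argued against, as the total of IP mock replicate 2 was 3.46 times the median library, and the shallowest library, input mock replicate 3, lacked fewer genes at 5 to 10 CPM (9.79%) than both inputs (24.2% and 23.7%). A gene missing from both of these inputs was found 225 times where independent loss among genes of like expression gives 129, a ratio of 1.75 (95% bootstrap interval 1.58 to 1.92), and with IP mock replicate 2 the ratio was 1.601 (1.49 to 1.69) for input mock replicate 2 and 1.34 (1.253 to 1.44) for input PE replicate 1. The bound of 1.5 set beforehand would exclude independent loss from the pair of inputs, but it assumes that genes of like expression are lost equally often, and with input mock replicate 3, outside these 3 libraries, the ratio was 1.49 (1.21 to 1.75) for input mock replicate 2 and 1.13 (0.886 to 1.38) for input PE replicate 1. As the first of these intervals holds 1.5 and overlaps that of 1.75, independent loss of molecules and loss of the same genes in both preparations cannot be told apart.

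The low number of genes that differed between PE and mock may come in part from spread added by the mock replicate 2 and PE replicate 1 libraries. Their deviations from the group means correlated with each other, between 0.159 and 0.273 in 6 of 6 pairs. Among the 81 ways to leave out 1 library of each group, leaving out these 4 gave the most genes in input, 8 against 0 to 4 (1 of 81 ways gave as many), and 36 in IP, where 2 of 81 ways gave as many and the highest other gave 46. With IP PE replicate 2 or 3 left out in place of IP PE replicate 1, IP gave 22 and 46 genes. The gain in IP thus does not rest on IP PE replicate 1. As these 4 libraries were picked from the same counts, a gain without them was likely beforehand and cannot decide the cause. A small effect of PE on transcript levels stays open as untested.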
